A study of Homo sapiens with 4 samples.

How the data were processed

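Gene expression was measured by RNA sequencing in 4 libraries of the human lung cancer line PC9: 2 of the parental cells and 2 of PC9-BrM4, a subline recovered from mouse brain. Per the labels' protocols, RNA was purified on silica columns, polyadenylated transcripts were selected, strand-marking libraries were made, and fragments were sequenced from both ends. The sample titles and the experiment field name the subline BrM4 and give 4 rounds of selection, while its cell-type field says BrM3; it is called PC9-BrM4 throughout. The melanoma cells that the series design also names were not analysed here.

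Each library had 1 deposited table of gene identifiers and values. The tables' headers name the library and no unit. The values were taken as FPKM, fragments per kilobase of transcript and 1000000 fragments, because the submitters' processing notes list Cufflinks and because the values are not whole numbers and do not sum to 1000000. The submitters' processing notes name Trim Galore 0.5.0, TopHat2 2.0.9, Cufflinks 2.1.1 and the GRCh38 build. The role and settings of each tool, the gene annotation, the strand setting and any scaling between libraries are not given in the sources used here. FPKM is a relative unit, so a few very abundant transcripts in a library lower the values of all others. FPKM also rests on an effective transcript length, which is poorly defined for transcripts shorter than the sequenced fragments. Because Cufflinks shares fragments between transcripts by an iterative estimate and not as whole fragments, counts could not be recovered, and the depth of each library is unknown. No counting interval is given for that reason, and a value of exactly 0 is reported as listed at 0, since it can be a failed estimate.

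Each table held 58118 lines for 58025 distinct gene identifiers. A total of 92 identifiers occupied 185 lines, and their values were summed. Names, types and GRCh38 coordinates came from GENCODE 29: 53676 identifiers matched with their version and 3745 without it, and 604 had no name. This annotation may differ from the one the authors used.

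Genes with at least 1 FPKM in at least 2 of the 4 libraries were tested, which left 13972 genes. Values were compared on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3, using moderated statistics with an intensity trend in the prior variance, and p-values were adjusted by the Benjamini-Hochberg method. The design held the group alone. A gene was called at an adjusted p under 0.05, and genes with a change of at least 2-fold on this scale were also counted. The log2 fold changes of genes with low FPKM are understated by the pseudocount of 1. Where a fold is given without a log2 sign, it is the ratio of the mean FPKM of the groups. Means are given with the standard deviation of the duplicates. With 2 residual degrees of freedom per gene the test leaned on the variance shared across genes, at 3.13 prior degrees of freedom. An exact permutation test of a single gene at 2 against 2 cannot go below a two-sided p of 0.33, so none was used. Nothing in the labels says that the duplicates came from separate cultures; the p-values therefore measure only the spread between these samples, which may be technical.

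Before the data were examined, 38 gene lists were fixed for the cell type, the selection in brain and the handling of the cells. The 37 lists with at least 5 tested genes were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01, and adjusted over the lists. The same test was run with the correlation estimated from the data. In that form camera refers its statistic to the 2 residual degrees of freedom, so even a strong shift can hardly pass adjustment over 37 lists. For each list the called members were counted with adjustment over all tested genes and adjusted over the list alone. Several lists share genes, such as ATF3, so their results are not independent.

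The named genes followed a rule set before the data were examined. It takes first the 12 largest increases and 12 largest decreases among called genes with the same sign in all pairings of a PC9-BrM4 with a parental library and at least 5 FPKM in both libraries of the higher group. Genes without a symbol, Y-linked genes and XIST were left out of that ranking. It takes second up to 3 called members of each list with the largest change, or the member with the smallest p where none was called. It takes last EGFR and all tested members of the list of published mediators of brain metastasis, with each library's value. Other genes are named in the text as chosen after their values were seen. Some genes that the rule takes are not reported here.

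The fit was tested on simulated data built on the 13972 genes of this comparison, with known changes in 50 genes of each size. It recovered 4% of genes changed 1.25-fold, 36% at 1.5-fold, 70% at 2-fold and 86% at 4-fold, with 3 false calls among 101. With no gene changed it made 0 calls. The list test found a planted list of 20 genes shifted 1.3-fold, and passed 6 of 200 random lists at the 0.05 level. Noise was drawn independently for each gene, so the random lists do not test the preset correlation between genes. Changes of single genes were planted only at a mean of about 5 FPKM or more, and in far fewer genes than were called in the libraries.

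Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values, a minimum of 5 FPKM, rescaling each library to a sum of 1000000 (TPM), median-of-ratios scaling, quantile normalization, a prior variance without trend, the replicate number as a block, an estimated correlation in the list test, and leaving out each library in turn. When a library is left out its group keeps 1 sample, which is assumed to vary like the other group, and genes above 1 FPKM only in that group are no longer tested. Alternatives added after the data were seen were protein-coding genes alone, no genes with a median transcript under 200 bases, and rescaling to a sum of 1000000 over protein-coding genes.

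For the closing section, the median log2 fold change of windows of 50 neighbouring genes was compared with 10000 reassignments of genes to positions, and windows beyond the 95th percentile of the largest window median were joined into regions. This was done in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and repeated with 25 and 100 genes per window. To check GC content, transcript length and expression level, a spline of these 3 was fitted to the log2 fold changes of the 99.4% of tested genes with values for them.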

Results

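Polyadenylated RNA was sequenced from PC9 cells, a human lung cancer line with a deletion in the EGFR gene that expresses green fluorescent protein and firefly luciferase, and from PC9-BrM4 cells. PC9-BrM4 is a subline obtained by 4 rounds of injecting the cells into the left ventricle of nude mice, collecting the brains around day 33, and growing out the tumour cells under antibiotic selection. Each line was represented by 2 libraries, prepared from cells in culture. The comparison asks which transcripts differ between cells selected for growth in brain and the line they came from. The tables hold FPKM and no counts, so depth is unknown. FPKM summed to 690416 and 659225 in parental 1 and 2, and to 618017 and 615163 in PC9-BrM4 1 and 2. Between 13632 and 13767 genes reached 1 FPKM in each library. Over tested genes the correlation of log2(FPKM + 1) was 0.981 between the parental duplicates and 0.979 between the PC9-BrM4 duplicates, and 0.956 to 0.962 between libraries of different lines; it is taken across genes, which are not independent replicates. The median absolute log2 difference was 0.10 and 0.11 within lines and 0.22 to 0.24 between them. The libraries also differed in mitochondrial tRNA genes, which took 13.8% and 8.08% of the FPKM sum in parental 1 and 2 and 2.81% and 4.08% in PC9-BrM4 1 and 2.

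CEACAM6, a carcinoembryonic antigen family protein anchored to the cell surface, fell from 138 ± 1.21 to 2.63 ± 0.234 FPKM (SD, n = 2) between parental and PC9-BrM4 cells, a 52.4-fold difference. CALML5, a calmodulin-like protein of differentiating keratinocytes, rose 29.4-fold from 2.59 ± 0.107 to 76.1 ± 8.54 FPKM (SD, n = 2). KRT5, a keratin of basal epithelial cells, rose 5.88-fold from 27.2 ± 1.09 to 160.1 ± 3.14 FPKM. LCP1, an actin-bundling protein best known from leukocytes, fell 7.33-fold from 169 ± 2.93 to 23.1 ± 0.116 FPKM. The limma adjusted p was 6.38e-05 for CEACAM6, 0.000214 for CALML5, 0.000167 for KRT5 and 6.63e-05 for LCP1. In the GRCh38 annotation these genes are CEACAM6 (ENSG00000086548.8, chromosome 19, 41750977 to 41772208), CALML5 (ENSG00000178372.7, chromosome 10, 5498697 to 5499555), KRT5 (ENSG00000186081.11, chromosome 12, 52514575 to 52520687) and LCP1 (ENSG00000136167.13, chromosome 13, 46125920 to 46211871).

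Among the other protein-coding genes with the largest increases, ARRB1, which encodes beta-arrestin 1, rose 6.19-fold from 8.37 ± 0.316 to 51.8 ± 4.37 FPKM (SD, n = 2). XYLT1, the xylosyltransferase that starts glycosaminoglycan chains, rose 13.9-fold from 0.557 ± 0.0757 to 7.73 ± 0.633 FPKM, and the collagen VI chain COL6A3 rose 32.3-fold from 0.230 ± 0.0409 to 7.42 ± 0.662 FPKM. CPVL, a carboxypeptidase, was listed at 0 and 0.0391 FPKM in the parental libraries and at 7.05 and 6.18 FPKM in PC9-BrM4. Among the largest decreases, PTN, which encodes the growth factor pleiotrophin, fell from 10.8 ± 0.0902 to 0.0830 ± 0.0383 FPKM (SD, n = 2). INHBA, the beta A subunit of activin, fell 7.79-fold from 24.96 ± 1.51 to 3.21 ± 0.763 FPKM, and the carboxypeptidase CPA4 fell 8.59-fold from 40.1 ± 4.69 to 4.67 ± 2.08 FPKM. COL17A1, the transmembrane collagen of hemidesmosomes, fell 9.12-fold from 12.5 ± 0.303 to 1.37 ± 0.0650 FPKM, and SCEL, a precursor of the cornified envelope, fell 9.55-fold from 12.8 ± 0.105 to 1.34 ± 0.1001 FPKM. EEF1A2, a translation elongation factor, fell 6.78-fold from 62.2 ± 4.71 to 9.18 ± 0.134 FPKM, and PKIB, an inhibitor of protein kinase A, fell 12.02-fold from 12.4 ± 0.0890 to 1.03 ± 0.240 FPKM. TMEM265 fell from 16.7 and 9.98 FPKM to 0.00279 and 1.66 FPKM. TMEM265 (adjusted p = 0.0744 without parental 1, 0.00695 to 0.1 over all alternatives) lost its call when 1 library was left out. Several of these genes lie in stretches of chromosome whose genes shifted together by a smaller amount. LCP1 lies on chromosome 13 (median log2 fold change of the stretch -0.32), PTN and CPA4 on chromosome 7 (-0.29) and ARRB1 on chromosome 11 (0.22). KRT5 rose within a stretch of chromosome 12 with a median of -0.39.

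Protein-coding genes held 6 of the 12 places for increases and 10 of the 12 for decreases. The remaining places went to short or non-coding genes and pseudogenes, whose values are uncertain because fragments can be shared with a parent gene or an overlapping gene, and because the strand setting is unknown. The mitochondrial serine tRNA gene MT-TS1 was listed at 63680 and 38320 FPKM in the parental libraries and at 0 in both PC9-BrM4 libraries. TMSB4XP6, a processed pseudogene of thymosin beta 4, was listed at 77.9 and 27.4 FPKM and then at 0 in both PC9-BrM4 libraries. In the other direction, the small nucleolar RNA gene SNORD15B was listed at 0 in both parental libraries and at 29.6 and 35.7 FPKM in PC9-BrM4. The processed pseudogene E2F6P4 was listed at 0 and then at 9.08 and 8.40 FPKM. BTF3P2, a further processed pseudogene, was at 0 and 0.0371 FPKM and then at 16.1 and 11.5 FPKM. AC000041.1, an unprocessed pseudogene, had values too close to 0 for a fold in the parental libraries, against 11.6 and 14.4 FPKM. AP001972.5 rose 12.9-fold from 1.52 ± 0.164 to 19.6 ± 1.04 FPKM (SD, n = 2). It lies beside ARRB1 on chromosome 11. SNORD15B lies further along that chromosome, at 75404421 to 75404566 against 75264182 to 75351705 for ARRB1. AC241644.3 rose 13.9-fold from 1.45 ± 0.945 to 20.1 ± 0.712 FPKM. It is annotated antisense to GJA5, a connexin gene chosen here after its values were seen, which rose from 0.724 ± 0.0256 to 8.19 ± 0.168 FPKM.

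**Figure D1:**
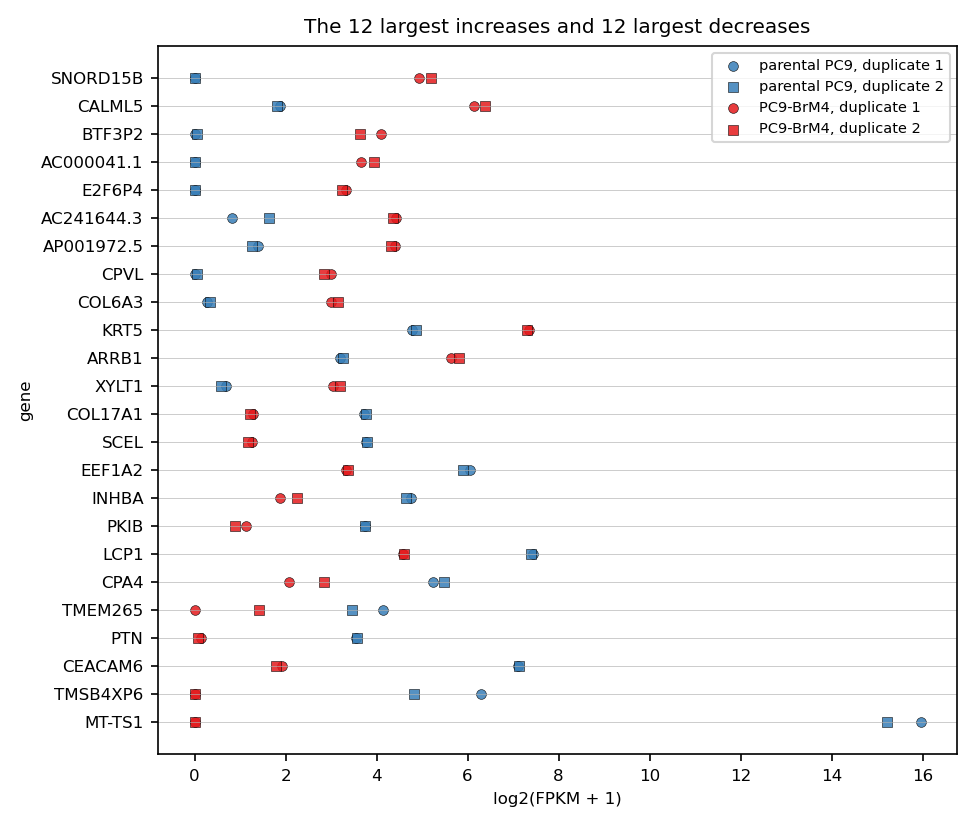
Expression of the 12 genes with the largest increases and the 12 with the largest decreases among called genes, as log2(FPKM + 1) on the horizontal axis, with 1 gene per line. Blue marks are the parental libraries and red marks the PC9-BrM4 libraries, circles for duplicate 1 and squares for duplicate 2; the duplicates of CEACAM6 lie at 137 and 139 FPKM in parental cells and at 2.80 and 2.47 FPKM in PC9-BrM4.

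Across all 13972 tested genes, 1588 were higher and 1583 lower in PC9-BrM4 at an adjusted p under 0.05 by limma, and 190 were higher and 249 lower by at least 2-fold. Of the 11830 protein-coding genes tested, 1439 were higher and 1436 lower. The libraries of the lines did not overlap in 9139 genes, or 65.4%, where chance gives 33.3%. Rescaling each library to a sum of 1000000 (TPM) moved the median log2 fold change of all genes from 0.01 to 0.13 and turned the split into 2679 higher and 992 lower, from 50.1% higher to 73% higher. The number of calls rested on having both duplicates: it was 887 without parental 1, 999 without parental 2, 1970 without PC9-BrM4 1 and 1818 without PC9-BrM4 2, against 3171 with all libraries. At 2-fold or more, 273 genes were called without parental 1 against 439, with 120 lower without parental 1 and 131 lower without parental 2 against 249, and 109 higher without PC9-BrM4 2 against 190.

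Of the genes reported in earlier work to mediate brain metastasis, L1CAM, an adhesion molecule by which tumour cells spread along brain capillaries, rose 2.88-fold, at 28.8 and 23.1 against 76.2 and 73.4 FPKM in parental 1 and 2 against PC9-BrM4 1 and 2. The calcium-binding protein gene S100A4 rose 1.95-fold, at 251 and 239.9 against 488 and 471 FPKM. Its relative S100A9 (log2 fold change 0.76) was at 4.57 and 5.16 against 8.76 and 9.11 FPKM, the sialyltransferase gene ST6GALNAC5 (0.77) at 0.988 and 0.957 against 2.08 and 2.67 FPKM, and the glucose transporter gene SLC2A1 (0.36) at 264 and 260.2 against 343 and 329.5 FPKM, in a higher stretch of chromosome 1; all 3 were called higher. S100A9 (adjusted p = 0.0657 without parental 1, 0.00643 to 0.0657 over all alternatives) and ST6GALNAC5 (adjusted p = 0.128 without parental 1 and 0.127 without parental 2, 0.0169 to 0.128 over all alternatives) lost their calls when 1 library was left out. CDH2, which encodes N-cadherin, fell 5.61-fold, at 5.64 and 5.30 against 0.975 and 0.975 FPKM. PTGS2, which encodes cyclooxygenase-2, fell 5.38-fold, at 2.28 and 1.88 against 0.357 and 0.415 FPKM. PTGS2 was called in 12 of its 13 alternatives, with a highest limma adjusted p of 0.0537. The epidermal growth factor family ligand gene HBEGF fell, at 21.9 and 22.2 against 14.1 and 14.6 FPKM. EGFR itself was at 145 and 143 against 157 and 157 FPKM (log2 fold change 0.13, adjusted p = 0.0621).

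Of 21 tested mediators, 5 were higher and 8 lower (6 and 10 adjusted over the list alone; camera adjusted p = 0.289); the other 9 were below the minimum level. Smaller decreases were called for SPOCK1 (15.8 and 17.1 against 8.48 and 9.59 FPKM, log2 fold change -0.80), PLEKHA5 (16.7 and 16.3 against 10.9 and 10.7 FPKM, -0.57), VEGFA (43.6 and 40.5 against 35.0 and 29.9 FPKM, -0.37), ITGB4 (82.5 and 82.2 against 66.0 and 61.8 FPKM, -0.36) and ITGAV (22.1 and 22.5 against 16.9 and 18.3 FPKM, -0.33). No call was made for CTSS (3.001 and 3.06 against 1.74 and 0.636 FPKM, adjusted p = 0.0687), LEF1 (3.76 and 2.49 against 1.80 and 1.94 FPKM, 0.129), ANGPTL4 (1.91 and 1.11 against 0.778 and 0.767 FPKM, 0.173) or SERPINI1 (3.71 and 3.32 against 4.04 and 1.69 FPKM, 0.542). Likewise none was made for ITGA6 (331 and 329 against 312 and 306 FPKM, 0.0899), CXCR4 (1.87 and 1.95 against 1.97 and 1.63 FPKM, 0.822), PCDH7 (6.85 and 5.38 against 6.15 and 6.04 FPKM, 0.985) or TWIST2 (5.26 and 4.01 against 6.37 and 6.92 FPKM, 0.0927). SPOCK1 (adjusted p = 0.0512 without parental 2, 0.00416 to 0.0512 over all alternatives) and PLEKHA5 (adjusted p = 0.0684 without parental 1 and 0.0572 without parental 2, 0.0061 to 0.0684 over all alternatives) lost their calls when 1 library was left out. ITGB4 (adjusted p = 0.0685 without parental 1 and 0.06 without parental 2, 0.00582 to 0.0685 over all alternatives) and VEGFA (adjusted p = 0.187 without parental 1, 0.106 without parental 2 and 0.104 without PC9-BrM4 2, 0.0297 to 0.187 over all alternatives) lost their calls when 1 library was left out. ITGAV (adjusted p = 0.132 without parental 1, 0.148 without parental 2, 0.105 without PC9-BrM4 1 and 0.0587 without PC9-BrM4 2, 0.026 to 0.148 over all alternatives) lost its call when 1 library was left out. A call appeared for CTSS (adjusted p = 0.0241 without PC9-BrM4 1, 0.0241 to 0.228 over all alternatives). EGFR was called higher at an adjusted p of 0.0185 after rescaling to TPM and 0.0357 after rescaling over protein-coding genes, within a range of 0.0185 to 0.25 over its alternatives, and TWIST2 at 0.0428 after rescaling to TPM, within 0.0428 to 0.302. Rescaling to TPM ended the calls of VEGFA, at 0.106, and ITGAV, at 0.137.

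**Figure D2:**
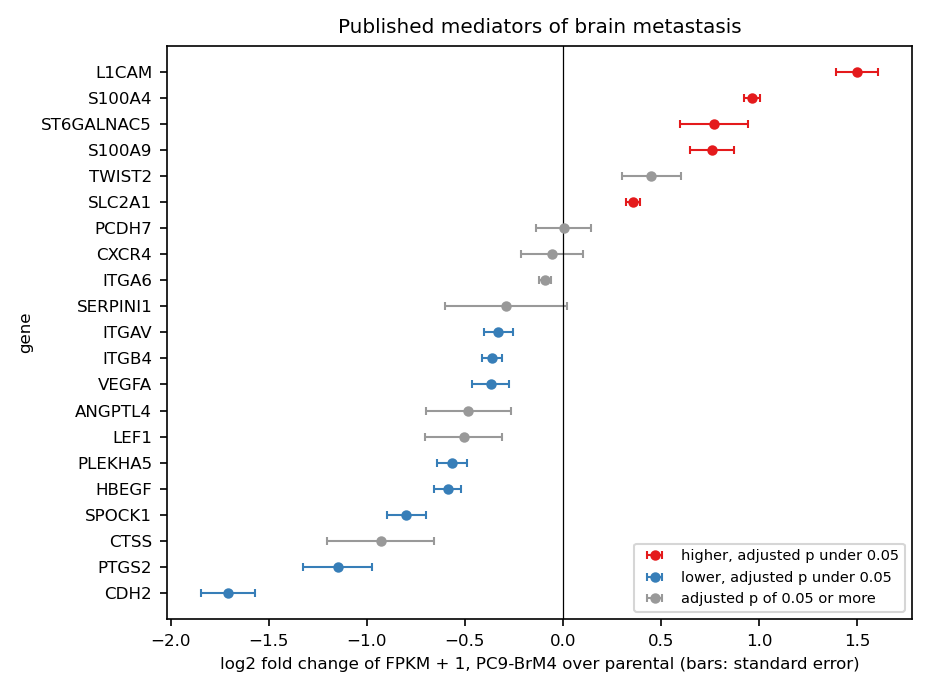
Log2 fold change of FPKM + 1 between PC9-BrM4 and parental cells for the 21 tested published mediators of brain metastasis, with bars for the standard error of the limma fit. Red points are the 5 genes called higher, blue points the 8 called lower and grey points the 8 not called; CDH2 stands at -1.71 and S100A4 at 0.96.

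Among receptors and ligands that signal beside EGFR, NRG1, which encodes neuregulin 1, fell from 3.66 ± 0.0470 to 0.488 ± 0.253 FPKM (SD, n = 2). NRG1 was called in 12 of its 13 alternatives, with a highest limma adjusted p of 0.052. The receptor tyrosine kinase genes AXL and MET fell, AXL from 165 ± 2.87 to 92.0 ± 3.29 and MET from 119.8 ± 4.85 to 77.8 ± 1.33 FPKM, while the fibroblast growth factor receptor gene FGFR3 rose 6.34-fold from 1.23 ± 0.0925 to 7.82 ± 0.589 FPKM. In the EGFR family and its ligands, 12 genes were tested, of which 0 were higher and 2 lower (0 and 2 adjusted over the list alone; camera adjusted p = 0.299); the lower ones were NRG1 and HBEGF. Of 15 other receptor tyrosine kinases and ligands, 1 was higher and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.838). The median of that list was 0.01 and its mean 0.04 on the log2 scale, while the test statistic pointed down. The further lower member was EPHA2, named after its values were seen, which fell from 50.3 ± 0.495 to 40.7 ± 2.90 FPKM. Of 17 output and feedback genes of the MAPK pathway, 2 were higher and 4 lower (2 and 4 adjusted over the list alone; camera adjusted p = 0.523); PHLDA1 fell from 28.7 ± 0.147 to 18.4 ± 0.0443 FPKM, and the immediate early transcription factor gene EGR1 from 4.57 ± 0.502 to 2.099 ± 0.377 FPKM. MET lies in the lower stretch of chromosome 7 and PHLDA1 in that of chromosome 12. EGR1 (adjusted p = 0.0792 without parental 1, 0.111 without parental 2 and 0.0686 without PC9-BrM4 2, 0.0118 to 0.111 over all alternatives) and EPHA2 (adjusted p = 0.141 without parental 1, 0.117 without parental 2 and 0.0795 without PC9-BrM4 1, 0.0215 to 0.144 over all alternatives) lost their calls when 1 library was left out. The EPHA2 call was also lost after rescaling to TPM, at 0.144.

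Genes of the TGF-beta and BMP pathway were lower as a list. Of 16 tested members, 2 were higher and 9 lower (3 and 9 adjusted over the list alone; camera adjusted p = 0.00204). The list had an adjusted p = 0.669 with an estimated correlation, the highest of 7.0e-05 to 0.669 over its alternatives. Besides INHBA, ID4 fell from 4.92 ± 0.593 to 1.71 ± 0.115 FPKM (SD, n = 2). The ligand genes TGFB1 and TGFB2, named after their values were seen, fell from 35.6 ± 3.43 to 19.6 ± 0.971 and from 17.8 ± 2.08 to 9.58 ± 0.209 FPKM. TGFB2 was called in 15 of its 16 alternatives, with a highest limma adjusted p of 0.054. The 2 higher members, named after their values were seen, were the genes of the latent TGF-beta binding proteins LTBP3, from 48.7 ± 0.857 to 69.5 ± 2.90 FPKM, and LTBP2, from 20.8 ± 0.465 to 27.0 ± 1.44 FPKM. Of 18 YAP and TEAD targets, 3 were higher and 9 lower (3 and 9 adjusted over the list alone; camera adjusted p = 0.0554), and the list was not called. ANKRD1 fell from 8.47 ± 0.00652 to 1.77 ± 0.182, IGFBP3 from 194 ± 6.24 to 60.6 ± 3.90 and GADD45A from 49.9 ± 0.297 to 21.1 ± 0.141 FPKM. The higher members, named after their values were seen, were AMOTL1, from 14.8 ± 0.0967 to 26.4 ± 1.03, ARHGEF17, from 5.15 ± 0.607 to 8.22 ± 0.970, and WWC1, from 44.1 ± 0.760 to 53.7 ± 1.08 FPKM. That list was called lower in 6 of its 17 alternatives: its adjusted p was 0.0389 without parental 1, 0.0356 without parental 2 and 0.0327 without PC9-BrM4 2, within a range of 0.0187 to 0.669, the last with an estimated correlation. AMOTL1 lies in a higher stretch of chromosome 11. ID4 (adjusted p = 0.0612 without parental 1, 0.00395 to 0.0612 over all alternatives) and LTBP2 (adjusted p = 0.117 without parental 1, 0.0878 without parental 2 and 0.0847 without PC9-BrM4 2, 0.0147 to 0.117 over all alternatives) lost their calls when 1 library was left out. WWC1 (adjusted p = 0.11 without parental 1, 0.0809 without parental 2, 0.0651 without PC9-BrM4 1 and 0.0519 without PC9-BrM4 2, 0.0122 to 0.11 over all alternatives) and ARHGEF17 (adjusted p = 0.157 without parental 1, 0.081 without parental 2, 0.0569 without PC9-BrM4 1 and 0.127 without PC9-BrM4 2, 0.025 to 0.157 over all alternatives) lost their calls when 1 library was left out.

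Immediate early and stress genes that respond to tissue dissociation and handling were lower in PC9-BrM4 as a list. Of 22 tested members, 1 was higher and 10 lower (1 and 11 adjusted over the list alone; camera adjusted p = 1.83e-05). The list had an adjusted p = 0.632 with an estimated correlation, the highest of 7.55e-06 to 0.632 over its alternatives. ATF3 fell from 9.85 ± 0.896 to 2.15 ± 1.17 FPKM (SD, n = 2), and the phosphatase gene DUSP1 fell from 7.97 ± 0.171 to 2.33 ± 0.0408 FPKM. JUN and the heat shock protein gene HSPA1A, named after their values were seen, fell from 37.9 ± 0.334 to 23.9 ± 1.96 and from 248 ± 1.46 to 141 ± 2.06 FPKM. FOS was the 1 member called higher, from 3.31 ± 0.610 to 7.63 ± 1.85 FPKM. ATF3 is also a member of the list of amino acid synthesis genes and ATF4 targets. ATF3 (adjusted p = 0.0672 without parental 1 and 0.0516 without parental 2, 0.00545 to 0.0834 over all alternatives) and FOS (adjusted p = 0.0674 without parental 1, 0.0987 without parental 2 and 0.068 without PC9-BrM4 1, 0.0138 to 0.121 over all alternatives) lost their calls when 1 library was left out.

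Keratin genes went both ways. The 16 tested protein-coding genes with KRT as the root of their symbol, grouped after their values were seen, had 7 higher and 5 lower (camera adjusted p = 0.911 over 187 such families, 0.005 with the median of neighbouring genes taken off and 0.995 with an estimated correlation). KRT7 fell from 952 ± 12.2 to 528 ± 2.94 FPKM (SD, n = 2), and KRT19 and KRT18, named after their values were seen, fell from 686 ± 13.6 to 503 ± 5.71 and from 1429 ± 27.1 to 1091 ± 6.75 FPKM. The claudin gene CLDN3 rose from 4.80 ± 0.251 to 12.96 ± 0.945 FPKM and the occludin gene OCLN from 14.4 ± 3.03 to 24.5 ± 0.0840 FPKM. Of 23 epithelial markers, 7 were higher and 5 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.511). KRT8 and the tight junction scaffold gene TJP1, also named after their values were seen, were the other lower members, from 1598 ± 4.55 to 1357 ± 11.1 and from 55.3 ± 0.174 to 44.8 ± 1.15 FPKM. Among 8 markers of lung lineages, 1 was higher and 3 lower (1 and 3 adjusted over the list alone; camera adjusted p = 0.299). KRT5 was the higher one. The transcription factor genes FOXA1 and TP63 fell, from 13.1 ± 0.759 to 1.77 ± 0.0209 and from 1.82 ± 0.106 to 0.505 ± 0.0145 FPKM, and CAV1, named after its values were seen, fell from 468 ± 0.661 to 326 ± 1.81 FPKM. KRT7, KRT18 and KRT8 lie with KRT5 in the lower stretch of chromosome 12, whose median was -0.39 against -0.85, -0.39 and -0.24 for KRT7, KRT18 and KRT8. KRT19 lies in the lower stretch of chromosome 17 and CAV1 in that of chromosome 7. The neighbouring genes of KRT5, KRT7, KRT18 and KRT8 had medians of -0.36, -0.35, -0.37 and -0.37, so taking them off raised the fold changes of these keratins. The camera adjusted p of 0.005 for the keratin family therefore rests in part on taking off a shift shared along chromosome 12. OCLN (adjusted p = 0.065 without PC9-BrM4 1 and 0.0716 without PC9-BrM4 2, 0.0103 to 0.114 over all alternatives) and KRT8 (adjusted p = 0.0612 without parental 1 and 0.051 without parental 2, 0.00253 to 0.14 over all alternatives) lost their calls when 1 library was left out. TJP1 (adjusted p = 0.0902 without parental 1, 0.0852 without parental 2 and 0.0526 without PC9-BrM4 1, 0.0105 to 0.101 over all alternatives) and TP63 (adjusted p = 0.0626 without PC9-BrM4 1 and 0.0614 without PC9-BrM4 2, 0.00804 to 0.0626 over all alternatives) lost their calls when 1 library was left out. The calls of KRT8, at 0.14, and TJP1, at 0.101, were also lost after rescaling to TPM.

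Mesenchymal genes went both ways. Of 15 mesenchymal markers, 4 were higher and 5 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.584). SNAI2, a repressor of E-cadherin, fell from 10.1 ± 0.551 to 2.86 ± 0.179 FPKM (SD, n = 2), and vimentin, VIM, fell from 35.5 ± 0.141 to 23.03 ± 2.21 FPKM. The matrix glycoprotein gene TNC rose from 4.30 ± 0.402 to 13.1 ± 0.893 FPKM and SPARC from 23.6 ± 0.415 to 44.5 ± 1.73 FPKM. VIM and SPARC were named after their values were seen. The collagen gene COL1A1 rose from 3.31 ± 0.0445 to 6.54 ± 1.47 FPKM, and COL5A1, named after its values were seen, fell from 4.54 ± 0.405 to 2.53 ± 0.294 FPKM. S100A4, which rose, and CDH2, which fell, are also members. In the broader list of extracellular matrix proteins, with 24 tested, 6 were higher and 8 lower (7 and 11 adjusted over the list alone; camera adjusted p = 0.456). The laminin gene LAMA3 fell from 139 ± 2.22 to 60.9 ± 2.45 FPKM, and the laminin gene LAMB3, named after its values were seen, fell from 119 ± 3.36 to 56.4 ± 1.28 FPKM. COL6A2 and COL6A1, likewise named after their values were seen, rose beside COL6A3, from 18.4 ± 0.0110 to 35.6 ± 0.0885 and from 44.6 ± 0.174 to 56.3 ± 1.39 FPKM. Both lie on chromosome 21, in a stretch whose genes were higher. VIM (adjusted p = 0.0583 without parental 1 and 0.0534 without parental 2, 0.00482 to 0.0583 over all alternatives) and COL1A1 (adjusted p = 0.119 without parental 1, 0.104 without parental 2 and 0.0816 without PC9-BrM4 2, 0.0175 to 0.125 over all alternatives) lost their calls when 1 library was left out. COL5A1 (adjusted p = 0.158 without parental 1, 0.0989 without parental 2, 0.0597 without PC9-BrM4 1 and 0.101 without PC9-BrM4 2, 0.0193 to 0.158 over all alternatives) and COL6A1 (adjusted p = 0.0735 without parental 1 and 0.0695 without parental 2, 0.00757 to 0.0735 over all alternatives) lost their calls when 1 library was left out.

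Proteases and their inhibitors were lower as a list. Of 26 tested members, 3 were higher and 12 lower (4 and 15 adjusted over the list alone; camera adjusted p = 0.00576). The list had an adjusted p = 0.632 with an estimated correlation, the highest of 0.00156 to 0.632 over its alternatives. The cystatin gene CST1 fell from 2.84 ± 0.0342 to 0.141 ± 0.200 FPKM (SD, n = 2), and PLAU, which encodes urokinase, fell from 87.7 ± 1.65 to 35.2 ± 0.708 FPKM. The higher members, named after their values were seen, were PLAT, which encodes tissue plasminogen activator, from 9.65 ± 0.952 to 17.5 ± 0.709 FPKM, ADAM8, from 10.8 ± 0.198 to 15.8 ± 2.39 FPKM, and the metalloproteinase inhibitor gene TIMP3, from 70.7 ± 0.147 to 81.9 ± 1.39 FPKM. PLAT was called in 15 of its 16 alternatives, with a highest limma adjusted p of 0.0512. Of 12 integrins, 2 were higher and 6 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.299). ITGA5, the fibronectin receptor subunit, fell from 17.2 ± 0.605 to 8.74 ± 1.68 FPKM and ITGB6 from 17.8 ± 3.21 to 11.6 ± 0.409 FPKM, while ITGB8 rose from 4.71 ± 0.230 to 7.64 ± 0.400 FPKM. ITGA5 lies in the lower stretch of chromosome 12. ADAM8 (adjusted p = 0.133 without parental 1, 0.138 without parental 2 and 0.099 without PC9-BrM4 1, 0.0203 to 0.138 over all alternatives) and TIMP3 (adjusted p = 0.134 without parental 1, 0.122 without parental 2, 0.0589 without PC9-BrM4 1 and 0.0875 without PC9-BrM4 2, 0.014 to 0.134 over all alternatives) lost their calls when 1 library was left out. ITGA5 (adjusted p = 0.0619 without parental 1 and 0.0646 without parental 2, 0.00635 to 0.0749 over all alternatives) and ITGB6 (adjusted p = 0.119 without parental 2, 0.107 without PC9-BrM4 1 and 0.0909 without PC9-BrM4 2, 0.0252 to 0.148 over all alternatives) lost their calls when 1 library was left out. ITGB8 (adjusted p = 0.0847 without parental 1, 0.0986 without parental 2, 0.0552 without PC9-BrM4 1 and 0.0804 without PC9-BrM4 2, 0.0133 to 0.0986 over all alternatives) lost its call when 1 library was left out.

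In cell contacts, FAT1, an atypical cadherin, rose from 12.8 ± 0.0764 to 25.3 ± 3.50 FPKM (SD, n = 2) and PCDHGC3 from 0.717 ± 0.210 to 3.24 ± 0.155 FPKM, while CDH2 fell. Of 12 cadherins and protocadherins, 4 were higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.243). The list passed the threshold without parental 1, at an adjusted p of 0.0389 within a range of 0.0389 to 0.914 over its alternatives. Of 16 tight junction genes, 5 were higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.939). CXADR rose from 9.06 ± 0.587 to 17.2 ± 0.0250 FPKM and lies in the higher stretch of chromosome 21. CLDN12 fell from 20.2 ± 1.56 to 10.1 ± 1.04 FPKM and lies in the lower stretch of chromosome 7. FAT1 was called in 15 of 16 alternatives, PCDHGC3 in 12 of 13 and CLDN12 in 15 of 16. Their highest limma adjusted p was 0.0546, 0.0576 and 0.0503. Of 11 WNT pathway targets, 3 were higher and 4 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.68). TCF7 rose from 9.02 ± 0.124 to 17.9 ± 2.04 FPKM and the feedback gene NKD1 from 0.0405 ± 0.0372 to 2.27 ± 0.330 FPKM, while its relative NKD2 fell from 1.47 ± 0.0777 to 0.351 ± 0.275 FPKM. Of 11 Notch pathway genes, 1 was higher and 1 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.799). The ligand gene JAG1 fell from 33.0 ± 1.57 to 20.7 ± 0.955 FPKM, and the target NRARP rose from 9.14 ± 0.729 to 13.24 ± 0.186 FPKM. NKD2 (adjusted p = 0.117 without PC9-BrM4 1, 0.0206 to 0.117 over all alternatives) and NRARP (adjusted p = 0.111 without parental 1, 0.0637 without parental 2, 0.0757 without PC9-BrM4 1 and 0.0716 without PC9-BrM4 2, 0.0159 to 0.111 over all alternatives) lost their calls when 1 library was left out.

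Genes of cholesterol synthesis and uptake were lower as a list. Of 22 tested members, 1 was higher and 9 lower (2 and 10 adjusted over the list alone; camera adjusted p = 0.00723). The list had an adjusted p = 0.632 with an estimated correlation, the highest of 0.00188 to 0.632 over its alternatives. SREBF2, the transcription factor that drives the pathway, fell 2.24-fold from 25.3 ± 1.15 to 11.3 ± 0.830 FPKM (SD, n = 2), INSIG1 fell from 6.45 ± 0.168 to 3.12 ± 0.0498 FPKM and the sterol oxidase gene MSMO1 from 24.97 ± 0.149 to 13.9 ± 0.0618 FPKM. Genes of fatty acid metabolism went both ways: of 26 tested, 7 were higher and 6 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.995). Their median was 0.08 and their mean -0.01 on the log2 scale. The fatty acid synthase gene FASN rose from 45.2 ± 1.10 to 85.1 ± 6.79 FPKM, and the binding protein gene FABP5 and the acyl-CoA synthetase gene ACSL5 fell, from 59.7 ± 2.65 to 20.7 ± 2.12 and from 20.4 ± 0.177 to 11.2 ± 0.330 FPKM. INSIG1 (adjusted p = 0.0674 without parental 1 and 0.0566 without parental 2, 0.00486 to 0.0674 over all alternatives) lost its call when 1 library was left out.

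Genes of amino acid synthesis and targets of the stress factor ATF4 were lower as a list. Of 27 tested members, 1 was higher and 11 lower (2 and 13 adjusted over the list alone; camera adjusted p = 0.00562). The list had an adjusted p = 0.632 with an estimated correlation, the highest of 0.00161 to 0.632 over its alternatives. Besides ATF3, the stress transcription factor gene DDIT3 fell from 12.9 ± 7.07e-04 to 5.49 ± 0.615 FPKM (SD, n = 2) and CHAC1, which encodes a glutathione-degrading enzyme, from 5.07 ± 0.602 to 2.34 ± 0.600 FPKM. ASNS, the asparagine synthetase gene named after its values were seen, fell from 48.3 ± 2.52 to 28.9 ± 0.602 FPKM. CEBPB was the 1 higher member, from 44.1 ± 2.02 to 59.6 ± 4.52 FPKM, and was named after its values were seen. Of 30 NRF2 targets and detoxification genes, 9 were higher and 9 lower (9 and 10 adjusted over the list alone; camera adjusted p = 0.983). The median of that list was 0.03 and its mean -0.04 on the log2 scale. AKR1B10, an aldo-keto reductase gene, fell 4.51-fold from 192 ± 2.68 to 42.6 ± 1.90 FPKM, GSTM3 fell from 53.2 ± 3.83 to 26.3 ± 0.829 FPKM and CYP1A1 rose from 2.23 ± 0.379 to 5.42 ± 0.852 FPKM. Among aldehyde dehydrogenase genes named after their values were seen, ALDH3A1 fell from 344 ± 6.89 to 178 ± 0.226 FPKM and ALDH1A3 rose from 194 ± 4.13 to 357 ± 4.96 FPKM. DDIT3 lies in the lower stretch of chromosome 12, and AKR1B10 and ASNS in that of chromosome 7. ATF3 (adjusted p = 0.0672 without parental 1 and 0.0516 without parental 2, 0.00545 to 0.0834 over all alternatives) and CHAC1 (adjusted p = 0.0889 without parental 1, 0.126 without parental 2 and 0.0707 without PC9-BrM4 1, 0.0157 to 0.126 over all alternatives) lost their calls when 1 library was left out. CEBPB (adjusted p = 0.0616 without parental 1 and 0.0793 without parental 2, 0.00811 to 0.081 over all alternatives) and CYP1A1 (adjusted p = 0.0812 without parental 1, 0.0515 without parental 2 and 0.0585 without PC9-BrM4 1, 0.00829 to 0.0882 over all alternatives) lost their calls when 1 library was left out.

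Of 29 hypoxia and glycolysis genes, 5 were higher and 6 lower (8 and 9 adjusted over the list alone; camera adjusted p = 0.511). SLC16A3, which encodes a lactate exporter, rose from 65.0 ± 4.81 to 101 ± 1.502 FPKM (SD, n = 2), the glucose transporter gene SLC2A3 rose from 0.890 ± 0.407 to 2.33 ± 0.0632 FPKM, and the pyruvate dehydrogenase kinase gene PDK1 fell from 9.87 ± 0.0841 to 6.15 ± 0.506 FPKM. Of 37 nuclear genes of oxidative phosphorylation, 5 were higher and 8 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.243). NDUFB3 fell from 60.8 ± 0.943 to 44.0 ± 2.26 FPKM and COX6C from 163 ± 4.33 to 129 ± 10.2 FPKM, while ATP5PO, in the higher stretch of chromosome 21, rose from 81.3 ± 0.387 to 109 ± 7.17 FPKM. Of 13 protein-coding genes of the mitochondrial genome, 0 were higher and 1 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.995). The lower one was MT-ATP8, from 5236 ± 333 to 3949 ± 516 FPKM. SLC2A3 (adjusted p = 0.0677 without parental 1, 0.154 without parental 2, 0.124 without PC9-BrM4 1 and 0.116 without PC9-BrM4 2, 0.0237 to 0.154 over all alternatives) and PDK1 (adjusted p = 0.0916 without parental 1, 0.0884 without parental 2 and 0.0599 without PC9-BrM4 2, 0.0113 to 0.0916 over all alternatives) lost their calls when 1 library was left out. NDUFB3 (adjusted p = 0.0566 without parental 1, 0.00408 to 0.0566 over all alternatives) and COX6C (adjusted p = 0.0841 without parental 1 and 0.0996 without parental 2, 0.0121 to 0.104 over all alternatives) lost their calls when 1 library was left out. ATP5PO (adjusted p = 0.0583 without parental 1 and 0.0535 without parental 2, 0.00472 to 0.0593 over all alternatives) and MT-ATP8 (adjusted p = 0.0893 without parental 1 and 0.138 without parental 2, 0.0118 to 0.187 over all alternatives) lost their calls when 1 library was left out. The calls of COX6C, at 0.0975, and MT-ATP8, at 0.111, were also lost after rescaling to TPM.

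Of 35 proliferation genes, 11 were higher and 4 lower (16 and 6 adjusted over the list alone; camera adjusted p = 0.0564). The thymidylate synthase gene TYMS rose from 83.8 ± 3.71 to 119 ± 0.335 FPKM (SD, n = 2) and the cell cycle factor gene E2F1 from 23.7 ± 1.14 to 34.1 ± 1.55 FPKM, while TOP2A, in the lower stretch of chromosome 17, fell from 89.4 ± 0.186 to 62.6 ± 0.163 FPKM. MKI67, named after its values were seen, rose from 46.9 ± 2.88 to 62.7 ± 2.72 FPKM. The list passed the threshold in 4 of its 17 alternatives, with adjusted p of 0.00663 without a filter on low values, 0.0153 after rescaling to TPM, 0.0221 without PC9-BrM4 2 and 0.0298 after rescaling over protein-coding genes. It was at 0.669, the highest value, with an estimated correlation. Of 20 p53 targets and senescence genes, 0 were higher and 8 lower (0 and 8 adjusted over the list alone; camera adjusted p = 0.149). The cell cycle inhibitor gene CDKN1A fell from 14.7 ± 1.27 to 7.27 ± 0.147 FPKM, GDF15 from 3.71 ± 0.447 to 1.10 ± 0.239 FPKM and TP53I3 from 14.2 ± 0.118 to 9.68 ± 0.596 FPKM. Of 13 replication-dependent histone genes, 0 were higher and 2 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.243); these were HIST1H2BD, from 21.9 ± 1.44 to 16.1 ± 1.14 FPKM, and HIST1H2BK, from 191 ± 22.7 to 151 ± 2.22 FPKM. Their levels are uncertain in polyadenylated RNA. E2F1 (adjusted p = 0.0563 without parental 2, 0.00552 to 0.0563 over all alternatives) and MKI67 (adjusted p = 0.0734 without parental 1, 0.00769 to 0.0734 over all alternatives) lost their calls when 1 library was left out. GDF15 (adjusted p = 0.0744 without parental 1 and 0.0518 without parental 2, 0.00494 to 0.0744 over all alternatives) and TP53I3 (adjusted p = 0.0922 without parental 1, 0.0903 without parental 2 and 0.0585 without PC9-BrM4 1, 0.012 to 0.0922 over all alternatives) lost their calls when 1 library was left out. HIST1H2BD (adjusted p = 0.136 without parental 1, 0.0731 without parental 2 and 0.0831 without PC9-BrM4 1, 0.0187 to 0.136 over all alternatives) and HIST1H2BK (adjusted p = 0.0907 without parental 2, 0.111 without PC9-BrM4 1 and 0.0992 without PC9-BrM4 2, 0.0268 to 0.2 over all alternatives) lost their calls when 1 library was left out. After rescaling to TPM, HIST1H2BD was at 0.0576 and HIST1H2BK at 0.2.

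Of 61 ribosomal protein genes, 6 were higher and 19 lower (7 and 20 adjusted over the list alone; camera adjusted p = 0.0477). The list was called in 8 of its 17 alternatives, with adjusted p from 0.00449 to 0.892. The call was lost without PC9-BrM4 1 (adjusted p = 0.218), without a filter on low values (0.0546), without an intensity trend (0.215), with the replicate block (0.0737), among protein-coding genes (0.0609) and with an estimated correlation (0.669). It was also lost under the 3 scalings that turned its direction. The median change of the list was -0.03 on the log2 scale, and it turned to 0.10 after rescaling to TPM, 0.02 after quantile normalization and 0.003 after rescaling over protein-coding genes. RPL23 fell from 809.5 ± 7.97 to 524 ± 8.30 FPKM (SD, n = 2) and RPL27 from 920.0 ± 11.6 to 691 ± 21.4 FPKM, both in the lower stretch of chromosome 17. Ribosomal protein genes have many processed pseudogenes that can share fragments with them. Of 8 cancer-testis antigen genes, 4 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.105). This list passed the threshold in 1 of its 17 alternatives, without a filter on low values (adjusted p = 0.0409). CTAG2 was listed at 0 in both parental libraries and at 5.54 and 3.38 FPKM in PC9-BrM4, SSX2 rose from 20.8 ± 0.628 to 30.7 ± 0.673 FPKM, and SPANXB1 fell from 44.7 ± 0.0219 to 18.4 ± 2.30 FPKM. MAGEA3 and MAGEA6, named after their values were seen, rose from 99.9 ± 5.05 to 142 ± 0.413 and from 116 ± 3.21 to 132 ± 1.17 FPKM. These families have near-identical copies, so their values are uncertain. MAGEA6 (adjusted p = 0.186 without parental 1, 0.102 without parental 2, 0.076 without PC9-BrM4 1 and 0.0985 without PC9-BrM4 2, 0.0205 to 0.186 over all alternatives) lost its call when 1 library was left out.

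Inflammatory genes moved in both directions. Of 20 cytokines, chemokines and NF-kB targets, 3 were higher and 7 lower (3 and 8 adjusted over the list alone; camera adjusted p = 0.243). The adhesion molecule gene ICAM1 rose 3.94-fold from 3.15 ± 0.758 to 12.4 ± 1.18 FPKM (SD, n = 2), while the cytokine genes IL11 and IL1A fell, from 11.9 ± 0.370 to 2.00 ± 0.645 and from 4.45 ± 0.0157 to 0.582 ± 0.0895 FPKM. IL6, named after its values were seen, fell from 5.20 ± 0.851 to 1.41 ± 0.199 FPKM. The other higher members, named after their values were seen, were LCN2, from 207 ± 0.578 to 288 ± 4.35 FPKM, and IL32, from 3.50 ± 0.250 to 7.92 ± 0.774 FPKM. IL6 was called in 14 of 15 alternatives and IL32 in 15 of 16, with highest limma adjusted p of 0.0592 and 0.0539. Of 28 interferon-stimulated genes, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.944). BST2 rose from 0.236 ± 0.191 to 2.51 ± 0.458 FPKM and IRF7 from 2.58 ± 0.235 to 5.46 ± 0.521 FPKM, and ISG20 fell from 3.63 ± 0.588 to 1.03 ± 0.261 FPKM. Of 16 antigen presentation genes, 2 were higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.682). HLA-C rose from 113 ± 2.15 to 147 ± 3.96 FPKM, the invariant chain gene CD74 rose from 3.60 ± 1.08 to 7.89 ± 1.77 FPKM, and CD274, which encodes PD-L1, fell from 6.61 ± 1.22 to 2.59 ± 0.524 FPKM. IL11 lies in the lower stretch of chromosome 19, and ISG20 fell within a higher stretch of chromosome 15. BST2 (adjusted p = 0.0542 without parental 1, 0.00388 to 0.0586 over all alternatives) and IRF7 (adjusted p = 0.0621 without parental 1, 0.0736 without parental 2 and 0.0608 without PC9-BrM4 2, 0.00772 to 0.0744 over all alternatives) lost their calls when 1 library was left out. ISG20 (adjusted p = 0.0544 without parental 1 and 0.0741 without parental 2, 0.00592 to 0.0774 over all alternatives) and CD74 (adjusted p = 0.133 without parental 1, 0.0523 without parental 2 and 0.12 without PC9-BrM4 2, 0.023 to 0.163 over all alternatives) lost their calls when 1 library was left out. CD274 (adjusted p = 0.0841 without parental 1 and 0.05 without PC9-BrM4 2, 0.00805 to 0.0898 over all alternatives) lost its call when 1 library was left out.

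No neuronal marker was called in either direction. Of 6 tested neuronal and neuroendocrine genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.299); ENO2 had the smallest p, at 12.8 ± 0.294 to 10.1 ± 0.704 FPKM (SD, n = 2) and an adjusted p of 0.0691. Of 11 neurotransmitter receptors and transporters, 1 was higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.465); this was the nicotinic receptor subunit gene CHRNA5, which rose from 9.26 ± 0.737 to 14.2 ± 0.562 FPKM. Of 26 axon guidance genes, 3 were higher and 7 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.456). The semaphorin genes SEMA3A and SEMA3B fell, from 5.80 ± 0.592 to 1.05 ± 0.556 and from 9.86 ± 1.05 to 5.37 ± 0.151 FPKM, and the ephrin gene EFNB1 fell from 18.5 ± 0.00643 to 10.8 ± 0.0725 FPKM. SEMA3A lies in the lower stretch of chromosome 7. CHRNA5 (adjusted p = 0.0571 without parental 1, 0.0781 without parental 2 and 0.0645 without PC9-BrM4 2, 0.00895 to 0.0781 over all alternatives) and SEMA3A (adjusted p = 0.0513 without parental 2, 0.00358 to 0.0677 over all alternatives) lost their calls when 1 library was left out. SEMA3B (adjusted p = 0.075 without parental 1, 0.00702 to 0.075 over all alternatives) lost its call when 1 library was left out.

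Few markers of other cell types reached the minimum level. Below it, SLC1A3 and MAG of the astrocyte and oligodendrocyte list, named after their values were seen, went opposite ways. SLC1A3 was at 0 and 0.187 FPKM in the parental libraries and at 0.608 and 1.32 in PC9-BrM4. MAG was at 1.38 and 0.882 FPKM in the parental libraries and at 0.462 and 0.217 in PC9-BrM4. Of 6 tested astrocyte and oligodendrocyte markers, 0 were higher and 2 lower (0 and 3 adjusted over the list alone; camera adjusted p = 0.299); CLU fell from 252 ± 1.18 to 212 ± 3.99 FPKM (SD, n = 2) and APOE from 1.60 ± 0.164 to 0.392 ± 0.119 FPKM. Of 6 fibroblast, pericyte and endothelial markers, 1 was higher and 0 lower (1 and 0 adjusted over the list alone; camera adjusted p = 0.703); this was COL1A1. Of 18 listed microglia and immune cell markers, 2 reached the minimum level, too few for a list test. Of these, 0 were higher and 1 lower (1 and 1 adjusted over the list alone). CD68 fell from 49.0 ± 1.23 to 34.3 ± 3.24 FPKM. CLU (adjusted p = 0.0727 without parental 1 and 0.0686 without parental 2, 0.00568 to 0.144 over all alternatives) and APOE (adjusted p = 0.0578 without PC9-BrM4 1 and 0.0832 without PC9-BrM4 2, 0.011 to 0.0832 over all alternatives) lost their calls when 1 library was left out. CD68 (adjusted p = 0.0763 without parental 1 and 0.0584 without parental 2, 0.00708 to 0.0763 over all alternatives) and COL1A1 (adjusted p = 0.119 without parental 1, 0.104 without parental 2 and 0.0816 without PC9-BrM4 2, 0.0175 to 0.125 over all alternatives) lost their calls when 1 library was left out. The CLU call was also lost after rescaling to TPM, at 0.144. PC9-BrM4 was recovered from mouse brain, and no reads or mouse genome were used here. Whether mouse fragments were counted in its libraries was therefore not tested on reads. Abundant genes of fibroblasts and pericytes, named after their values were seen, stayed near 0 in the PC9-BrM4 libraries: COL3A1 at 0 and 0.062 FPKM, DCN at 0 and 0.063, LUM at 0 in both and COL1A2 at 0.165 and 0.353, against 0.075 and 0.322 in the parental ones. These levels were far below the rises of COL6A3 and COL1A1. They cannot decide whether cells of mouse stroma were a source of those rises. How many mouse fragments a human alignment counts for each gene is unknown here.

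**Figure D3:**
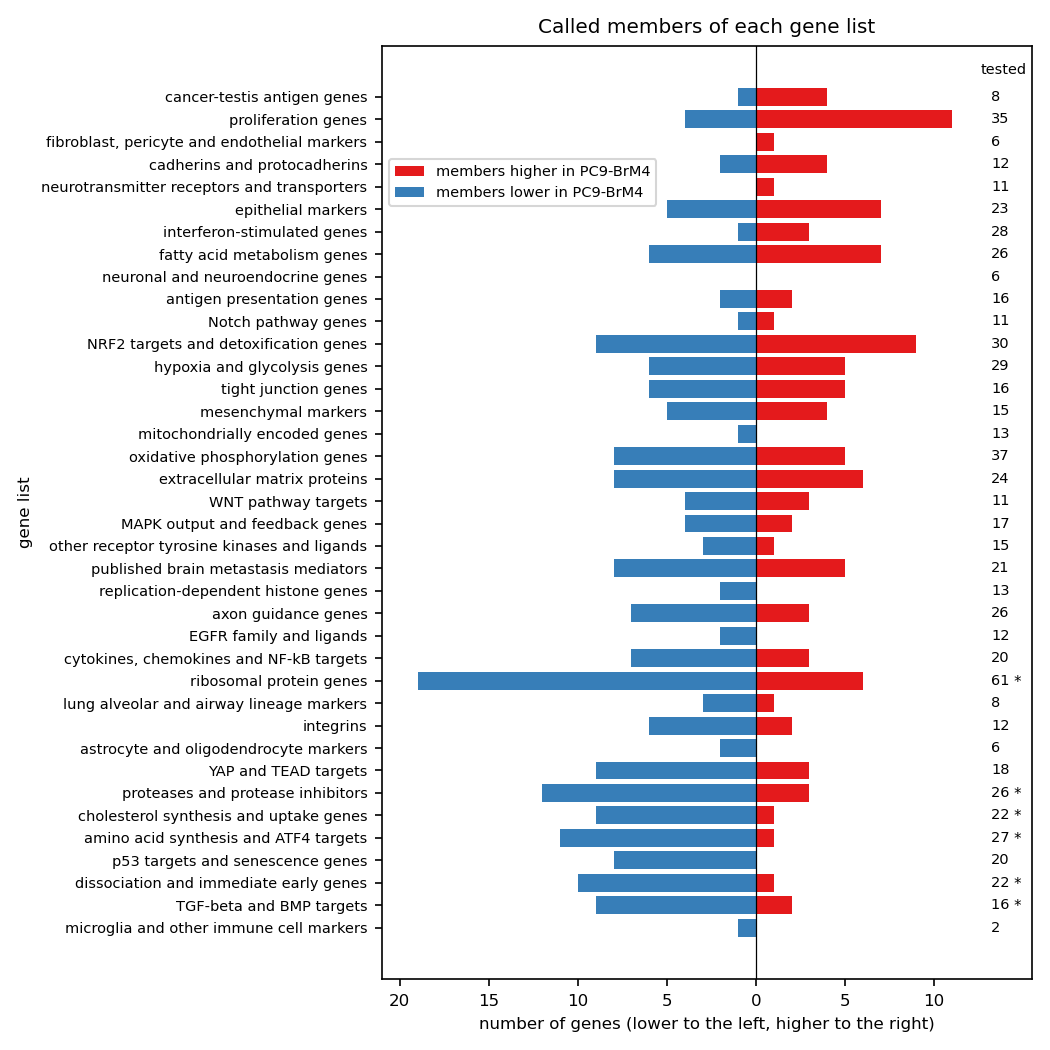
Number of called members in each of the 38 gene lists, with members lower in PC9-BrM4 to the left of 0 in blue and members higher to the right in red. The column at the right gives the tested genes, and an asterisk marks the 6 lists with a camera adjusted p under 0.05 at the preset correlation, of which 0 passed with an estimated correlation; the ribosomal protein list, among these 6, turned direction under 3 alternative scalings.

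Of the 37 lists that could be tested, 6 were called by camera at the preset correlation, all of them lower in PC9-BrM4: dissociation and immediate early genes, TGF-beta and BMP targets, ATF4 targets, proteases and their inhibitors, cholesterol genes and ribosomal proteins. None passed with an estimated correlation, where 0 lists had an adjusted p under 0.05. That outcome cannot decide the calls, because camera then rests on the 2 residual degrees of freedom. For proteases, cholesterol genes and ATF4 targets the estimated correlation (-0.0273, -0.0131 and 0.00215) was below the preset 0.01. Their unadjusted camera p still rose from 0.000623, 0.000977 and 0.000456 to 0.062, 0.0683 and 0.0619. For immediate early genes, TGF-beta targets and ribosomal proteins the estimate was above 0.01 (0.0376, 0.0828 and 0.102). The lists were compared with all other genes, so they describe a shift relative to the rest of the transcriptome.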

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

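The alternatives chosen after the data were seen were protein-coding genes alone, leaving out genes with a median transcript under 200 bases, and rescaling over protein-coding genes.

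The sizes of the gene counts depended on the processing, and the cause was not tested except where stated. Without a filter on low values 1015 genes were called (514 higher, 501 lower), of which 901 were among the 3171, and 218 of them changed at least 2-fold (103 higher, 115 lower); 26821 genes were then tested in place of 13972. At a minimum of 5 FPKM 220 genes changed at least 2-fold (101 higher, 119 lower), with 10029 genes tested. Rescaling to TPM gave 2679 higher and 992 lower, and 343 higher by at least 2-fold. By its construction this raised PC9-BrM4 values, since the parental FPKM sums were larger. Genes with a median transcript under 200 bases summed to 103839 and 72374 FPKM in parental 1 and 2. In PC9-BrM4 1 and 2 they summed to 25366 and 40315 FPKM. The results under TPM therefore rest in part on estimates for short genes, which may fail. Rescaling over protein-coding genes gave 298 higher by at least 2-fold. Without an intensity trend 2091 genes were called, 989 of them higher. Leaving out 1 library at a time left 1 sample in a group, and gave 887 to 1970 called genes (469 to 915 higher, 418 to 1055 lower), 273 to 397 at least 2-fold (109 to 165 higher, 120 to 262 lower), and 5 to 8 called lists. The lists called fell to 0 with an estimated correlation in place of 6.

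With the replicate number as a block 2033 genes were called (986 higher, 1047 lower) in place of 3171. The libraries share a number and nothing in the labels pairs them, and the deviations of same-numbered libraries correlated at -0.196 over genes, with 2 pairs.

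Over the named genes, 3089 comparisons of a gene with an alternative kept direction and side of the threshold, 389 lost the call, 6 gained one and 10 turned direction, all 10 of genes not called. Over the lists 567 kept both, 11 lost the call, 12 gained one and 35 turned direction, 32 of them of lists not called; the cause was not tested. The list called, ribosomal proteins, turned from a median log2 fold change of -0.03 to 0.099 after rescaling to TPM, 0.020 after quantile normalization and 0.003 after rescaling over protein-coding genes. Of lists not called, these medians turned without a filter on low values: other receptor tyrosine kinases -0.012, neurotransmitter receptors -0.001, WNT 0.019, Notch -0.024, antigen presentation -0.008, fatty acid metabolism -0.003 and fibroblast markers -0.023. At a minimum of 5 FPKM they were mesenchymal markers 0.025, matrix proteins 0.001 and fatty acid metabolism -0.001. After rescaling to TPM they were MAPK 0.062, axon guidance 0.032, matrix proteins 0.026, WNT 0.109, interferon 0.098, cytokines 0.045, oxidative phosphorylation 0.054, p53 targets 0.004 and mitochondrially encoded genes 0.114, with ITGA6 0.036, CXCR4 0.031, GALNT7 0.045 and GALNT10 0.074. Median-of-ratios scaling turned receptor tyrosine kinases to -0.006 and PCDH7 to -0.007. Quantile normalization turned receptor tyrosine kinases to -0.011, interferon to 0.006 and mitochondrially encoded genes to 0.089. Rescaling over protein-coding genes turned WNT to 0.034, interferon to 0.020 and mitochondrially encoded genes to 0.018. Ranges when 1 library was left out, with the library that turned them, were CXCR4 -0.144 to 0.031 (turned without PC9-BrM4 2), GALNT10 -0.147 to 0.040 (turned without parental 1), PCDH7 -0.145 to 0.154 (turned without parental 2 and PC9-BrM4 1), SERPINI1 -0.743 to 0.161 (turned without PC9-BrM4 2) and WNT -0.170 to 0.018 (turned without parental 2). The other ranges of this kind were interferon -0.085 to 0.010 (turned without parental 1), mesenchymal markers -0.467 to 0.200 (turned without parental 2), mitochondrially encoded genes -0.091 to 0.050 (turned without parental 2), neurotransmitter receptors -0.081 to 0.268 (turned without PC9-BrM4 2) and receptor tyrosine kinases -0.008 to 0.062 (turned without PC9-BrM4 2). The largest window of neighbouring genes was at 0.67, 0.49 and 0.54 with 25 genes, 100 genes and a minimum of 5 FPKM, each with a permutation p = 0.0001 over 10000 shuffles. Depth is unknown, so no limit of detection can be given for genes listed at 0.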

Other observations

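Chosen after the results were seen were the test of genes under 200 bases, the test of GC content, length and level on the chromosome 16 region, the test of GC content, length and level on the ribosomal protein genes, the gene families, and all genes named in the next 2 paragraphs.

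Among genes outside the lists fixed beforehand, SFRP1, a secreted antagonist of WNT ligands, rose 5.23-fold from 11 ± 0.449 to 57.5 ± 3.20 FPKM (SD, n = 2), and FBLN1, which encodes the matrix protein fibulin 1, rose 3.68-fold from 25.4 ± 2.23 to 93.5 ± 0.802 FPKM. The cell-surface peptidase genes ANPEP and DPP4 rose, from 33.2 ± 0.507 to 123 ± 1.85 and from 1.12 ± 0.513 to 9.40 ± 0.0573 FPKM, as did the water and glycerol channel gene AQP3, from 7.11 ± 1.02 to 25.5 ± 0.988 FPKM. KYNU, which encodes an enzyme of tryptophan breakdown, fell 5.39-fold from 49.6 ± 0.0458 to 9.20 ± 0.676 FPKM. The chemokine receptor gene ACKR3 fell 10.98-fold from 8.87 ± 0.143 to 0.808 ± 0.103 FPKM, the collagen gene COL8A1 fell 11.6-fold from 8.90 ± 1.22 to 0.764 ± 0.151 FPKM, and the adhesion gene NECTIN3 fell from 19.6 ± 3.14 to 3.73 ± 0.556 FPKM. The adjusted p by limma was 0.000481 for SFRP1, 0.000246 for ANPEP, 0.000508 for KYNU and 0.00145 for ACKR3. ANPEP lies in a higher stretch of chromosome 15 with a median of 0.25.

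The GALNT genes, whose enzymes start mucin-type O-glycan chains, were 1 of 2 families called lower among 187. The other was RPL, protein-coding genes grouped by the root of their symbol, with 3 higher and 20 lower of 49 and a median log2 fold change of -0.08 (adjusted p = 0.00531, and 0.995 with an estimated correlation) that turned to 0.05 after rescaling to TPM (0.779). The RPL call was also lost under quantile normalization (0.68), without an intensity trend (0.16) and after rescaling over protein-coding genes (0.0688). GALNT16 fell from 9.47 ± 0.842 to 3.24 ± 0.657 FPKM (SD, n = 2) and GALNT12 from 12.4 ± 1.20 to 5.63 ± 0.0411 FPKM, while GALNT2 rose from 50.9 ± 0.0488 to 67.9 ± 1.54 FPKM. GALNT16 lies in a lower stretch of chromosome 14. GALNT6, called lower, and GALNT4, not called, lie in that of chromosome 12. Their log2 fold changes were -0.45 and -0.41, against medians of -0.36 and -0.47 for their neighbouring genes. GALNT16 was called in 15 of its 16 alternatives, with a highest limma adjusted p of 0.0547, and GALNT12 in all 16. The other members called lower kept their calls less often. GALNT6 was called in 10 of 16 alternatives, GALNT11 in 11 of 16, GALNT3 in 9 of 16, GALNT5 in 9 of 15 and GALNT9 in 6 of 15. Of 14 tested members 1 was higher and 7 lower, with a median log2 fold change of -0.43 that stayed negative under TPM, median-of-ratios, quantile and protein-coding scaling (-0.36, -0.44, -0.42 and -0.45). Camera gave the GALNT family an adjusted p of 0.0389, and 0.0324 with the median of neighbouring genes taken off. The adjusted p was 0.995 with an estimated correlation, 0.0965 without PC9-BrM4 2, 0.119 at a minimum of 5 FPKM, 0.0516 among protein-coding genes and 0.055 after rescaling over them, within a range of 0.00711 to 0.995.

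Neighbouring genes moved together along whole stretches of chromosome. Over 13862 genes with a position, 16 regions were beyond the limit of 0.24 that shuffled genes gave for the median of 50 neighbours. The largest window was at 0.58 (permutation p = 0.0001, the smallest that 10000 shuffles can give). Among the regions were 346 genes on chromosome 12 (27022546 to 101407820, median -0.39, 147 lower and 7 higher) and 144 genes on chromosome 21 (5022493 to 46665124, median 0.33, 59 higher and 1 lower). The 16 regions held 15.3% of genes and 24% of calls. That excess follows from the way they were chosen, by the fold changes of these same libraries. The largest window was at 0.53 and 0.60 for each PC9-BrM4 library against the parental mean but 0.14 and 0.11 between duplicates. Local co-regulation of adjacent genes is argued against by gene pairs 5 to 10 Mb apart, which still correlated at 0.11 where 1000 shuffles reached 0.005. GC content, transcript length and expression level are argued against for the regions as a set, since 99.8% of their median absolute shift stayed after a spline of these was removed, but stay open for the chromosome 16 region, which kept 43.9% (SE 11.1); those on chromosomes 15 and X went from 0.25 to 0.20 and from -0.22 to -0.17. A gain or loss of chromosome segments in the subline may account for the regions but was not decided, and no DNA data were used here. Of 6 regions found in every second gene, all of them lower, 100% shifted the same way in the genes left out. Neighbouring genes would do so whatever the cause, since pairs 1 to 5 Mb apart correlated at 0.122 where 1000 shuffles reached 0.005. Pairs within 1 Mb were at 0.221, but that value counts each gene with itself, and shuffles reached 0.093.

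With neighbouring genes taken off, the 6 lists stayed called, and the YAP and TEAD (adjusted p = 0.0326), oxidative phosphorylation (0.0326) and proliferation lists (0.0215) passed too. These are calls at the preset correlation; with an estimated one and no correction, these 9 lists were at 0.632 to 0.669. Position is argued against for the 5 lists other than ribosomal proteins, whose members kept 93.6% (SE 3.8) of their mean log2 fold change of -0.37 with the neighbouring genes taken off, and GC content, length and level likewise, with 103.6% (SE 1.8) kept. After that spline the YAP and TEAD (adjusted p = 0.0145), proliferation (0.0489) and mitochondrially encoded lists (0.00338, mean from -0.02 to 0.16) passed as well, again at the preset correlation; the last was at 0.995 with an estimated one and no correction. The ribosomal protein genes differ: GC content, length and level could account for their small mean of -0.07, since -32.5% (SE 7.9) of it was left after a spline fitted without them, that is, the sign turned. How much position adds for the ribosomal protein genes was not settled, since the share of the mean kept, 80.2% (SE 25.8), has a wide error. As the whole cause position is argued against, at the main scaling alone. The mean stayed at -0.053 (SE 0.017) and the list stayed called (camera adjusted p = 0.00465 against 0.0477 before). Of 52 members outside the regions 16 were lower and 4 higher. The correction was not run under the scalings that turned the direction of this list. For the 5 other lists the selection in brain, the culture after it and the density or handling of the cells at harvest could not be separated, because any difference in these follows the lines and the labels do not say that the duplicates were separate cultures. Both PC9-BrM4 libraries came from the same subline. No independently selected subline was compared, so an effect of selection cannot be told from a trait of this subline.

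Genes of under 200 bases often differed widely between duplicates. MT-TS1 differed between the lines rather than in this way, at 63680 and 38320 FPKM in the parental libraries and at 0 in both PC9-BrM4 libraries. The estimate may fail for transcripts shorter than the sequenced fragments: of 79 such genes reaching 10 FPKM, 84.81% were listed at 0 in one duplicate and at 10 or more in the other, against 0.05% of 8142 longer genes. Real differences in short RNAs between the lines were not tested.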
